A study of Plasmodium falciparum with 4 samples.

How the data were processed

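Total RNA of Plasmodium falciparum from 4 cultures was measured on 4 oligonucleotide arrays, 1 per culture. Per the labels' protocols, parasites synchronised at the ring stage were kept in a serum-free medium and exposed to a drug for 12 h, RNA was extracted with TRIzol and column purification, and biotin-labelled cRNA was made with a GeneChip 3' IVT PLUS kit. Groups were taken from the labels: untreated, dihydroartemisinin, 7-benzylidenenaltrexone and rimonabant, with 1 array in each.

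The deposited values were linear intensities, 1 per probe set and array, made by the authors with Affymetrix Power Tools 1.15.0, per the submitters' processing notes. The background correction, the summary over probes and the normalization between arrays are not given in the sources used here. The highest value was 40132 on 3 arrays and 40294 on the rimonabant array, and the lowest lay between 3.81 and 3.93, which shows a linear scale and arrays already scaled to each other. Such a scaling over all 22699 probe sets, most of them of the mosquito, can hide or create a shift common to the parasite transcripts, so the splits into higher and lower were repeated under other scalings. Scanner files were not used here, and 0 sample columns were left unused.

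Values were raised to at least 1, which altered none, and log2 was taken. Of the probe sets, 4502 had IDs beginning with Pf and a point and 16884 IDs beginning with Ag and a point, taken as the parasite and mosquito sets of this array type. A parasite locus was the part of the ID made of Pf, the chromosome field and a number, which gave 4249 loci, 221 of them with several probe sets. Each locus was represented by its brightest probe set by mean over the 4 arrays. Probe sets whose IDs end in _x_at or _s_at can hybridise to more than 1 sequence. A locus was above background on an array when it exceeded that array's 95th percentile of the mosquito sets, an intensity of 8.72 for the untreated array, 9.15 for DHA, 8.99 for BNTX and 8.68 for rimonabant. Loci above background on at least 1 of the arrays compared were used: 3887 on at least 1 of the 4, and 3440 on all 4. For a locus not above background on the dimmer array, the fold is a bound computed against that array's cutoff.

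With 1 array per group no test between cultures was run and no p-value computed; the shuffles and random lists below describe these 4 arrays only. Loci were counted at 2-fold and 4-fold differences. Error was described by the SD over probe sets of the same transcript and by the spread of the mosquito probe sets, neither of which covers differences between cultures. Overlaps were set beside 1000 shuffles of each locus's values among the arrays after array medians were removed, and for correlations this was repeated under centring, quantile normalization and the addition of 32, after the data were seen. These shuffles keep the whole spread of each locus, real differences included. They move each locus separately, so their range leaves out loci that vary together and can be too narrow. Lists of loci sharing a chromosome field were set beside 10000 random lists of the same size matched on mean intensity in 20 bins. Shares of loci have Wilson 95% intervals, which cover counting error only.

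None of the IDs matched the 5615 genes of the reference gene table (assembly of strain 3D7): the number of matches was 0. The 32 gene lists fixed before the data were examined, among them the markers of parasite stages, therefore gave no result. The rule for named genes, also fixed before the data were examined, took for each drug the 10 highest and 10 lowest genes with a described product, at least 2-fold and with a probe set not ending in _x_at, plus the 2 highest and 2 lowest of any product, members of each list, the artemisinin-linked genes whatever their value, and 5 in each direction between drugs. Without gene names only its part on any product could be used, and it gave 2 loci in each direction per drug. Actin, GAPDH, hrpII and hrpIII were named because their IDs carry the name.

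The alternatives fixed before the data were examined were a 99th percentile cutoff, no filter on dim loci, the median over all probe sets of a locus, leaving out _x_at and _s_at probe sets, centring each array on its median over loci above background on all arrays, quantile normalization over the parasite probe sets, and adding 32 before log2. Raising dim values to the background cutoff was added after the data were seen. The counting was tested on simulated arrays of 4249 loci with a spread of 0.3 on the log2 scale per array, a value set by hand. Differences were given only to loci well above background, so recovery of dim loci was not simulated. Of loci given a 2.83-fold difference, 90% were recovered in the DHA simulation, 90% for BNTX and 88% for rimonabant, and of those given an 8-fold difference 100% in each. Among loci given no difference, 75, 77 and 61 passed 2-fold in those simulations, and the correlation of log2 ratios with no effect was 0.50, 0.50 and 0.48. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.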

Results

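Blood-stage Plasmodium falciparum, the malaria parasite that multiplies inside human red cells, was profiled on 4 GeneChip arrays. Parasites had been synchronised at the ring stage, the first stage after entry into a red cell, and grown without serum at 37 °C under 5% oxygen. There was 1 array each for an untreated culture, for a culture given dihydroartemisinin (DHA, an artemisinin-class antimalarial), for one given 7-benzylidenenaltrexone (BNTX, a naltrexone derivative that blocks opioid receptors) and for one given rimonabant (a blocker of cannabinoid receptors, spelled rimonaband in the labels). Drug exposure lasted 12 h. The labels used here give no doses and no separate incubation time for the untreated culture, which they describe only as normally developed. A difference in parasite stage between it and the treated cultures was not measured here, so each ratio below compares 2 cultures that can differ in stage as well as in drug. No group had a replicate, so the differences below have no replicate check, no test across cultures was possible, and the number of arrays limits the precision.

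The deposited values were linear intensities for 22699 probe sets. The median over an array was 6.48 for the untreated culture, 6.62 for DHA, 6.57 for BNTX and 6.46 for rimonabant. The 4502 probe sets whose IDs begin with Pf and a point, taken as those of the parasite, had medians of 119, 99.8, 95.1 and 116 on the same arrays. The 16884 probe sets of the mosquito (Anopheles) that share the array had medians between 6.16 and 6.31, and the highest intensity of any was 123. Above the 95th percentile of the mosquito sets, 3766 of 4249 parasite loci were detected in the untreated culture, 3569 under DHA, 3736 under BNTX and 3657 under rimonabant. The probe set IDs were not paired with gene names by any table used here, so gene groups fixed in advance could not be formed. Genes are named below only where the ID itself carries a name, and these were chosen after their values were seen. Other loci appear under their ID, in which the field after Pf is the chromosome field of the array design. The file gives no coordinates.

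The first comparison asked which transcripts differed in abundance in parasites exposed to DHA. Actin, the cytoskeletal protein that also drives red cell invasion, was 4.41-fold lower on the DHA array than on the untreated array, with a geometric mean intensity of 602 against 2656. The mean log2 ratio was -2.14 ± 0.23 (SD over 3 probe sets of the same transcript, which is spread within an array and not between cultures). All 3 actin sets are of the _s_at type, which can hybridise to more than 1 sequence. The transcript of hrpIII, a histidine-rich protein, was 2.52-fold lower, at 20.4 against 51.6, with a log2 ratio of -1.33 ± 0.13 over 2 probe sets, or -0.86 after quantile normalization. Of these 2 hrpIII sets, 1 is of the _x_at type, which can also hybridise to more than 1 sequence. GAPDH, an enzyme of glycolysis, had a log2 ratio of 0.05 ± 0.12 over 3 probe sets, and its sign turned to -0.03 under quantile normalization. The related hrpII probe sets were not above background on any of the 4 arrays.

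Among parasite loci without a name, Pf.13_1.639 had the highest ratio under DHA, with an intensity of 934 against 44.1, which is 21.2-fold higher. Pf.12.150 followed, 18.6-fold higher at 1141 against 61.4. At the other end, Pf.5.41 was 68.0-fold lower, at 23.2 against 1575. Its brighter probe set can hybridise to more than 1 sequence, and its other set went the same way, at 11.3 against 660. With 32 added before log2, the log2 ratio of Pf.5.41 went from -6.09 to -4.86. Pf.11.380 had an intensity of 358 in the untreated culture and was not above background under DHA, so that it was at least 39.1-fold lower.

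Of 3806 parasite loci above background on the DHA or the untreated array, 423 were at least 2-fold higher under DHA and 718 at least 2-fold lower, while 2665 lay within 2-fold. At 4-fold the numbers were 42 higher and 231 lower. The share of higher loci among those past 2-fold was 37.1% for the values as deposited, 50.7% with each array centred on its median, and 49.5% after quantile normalization of the parasite probe sets, so the excess of lower loci at 2-fold depended on the scaling. Centring removed differences between array medians, on the log2 scale, of -0.18 for DHA, -0.31 for BNTX and 0.05 for rimonabant against the untreated array. These are not medians of the ratios, which were -0.11 for DHA, -0.06 for BNTX and 0.18 for rimonabant as deposited. After centring the median ratios were 0.07, 0.24 and 0.12.

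**Figure D1:**
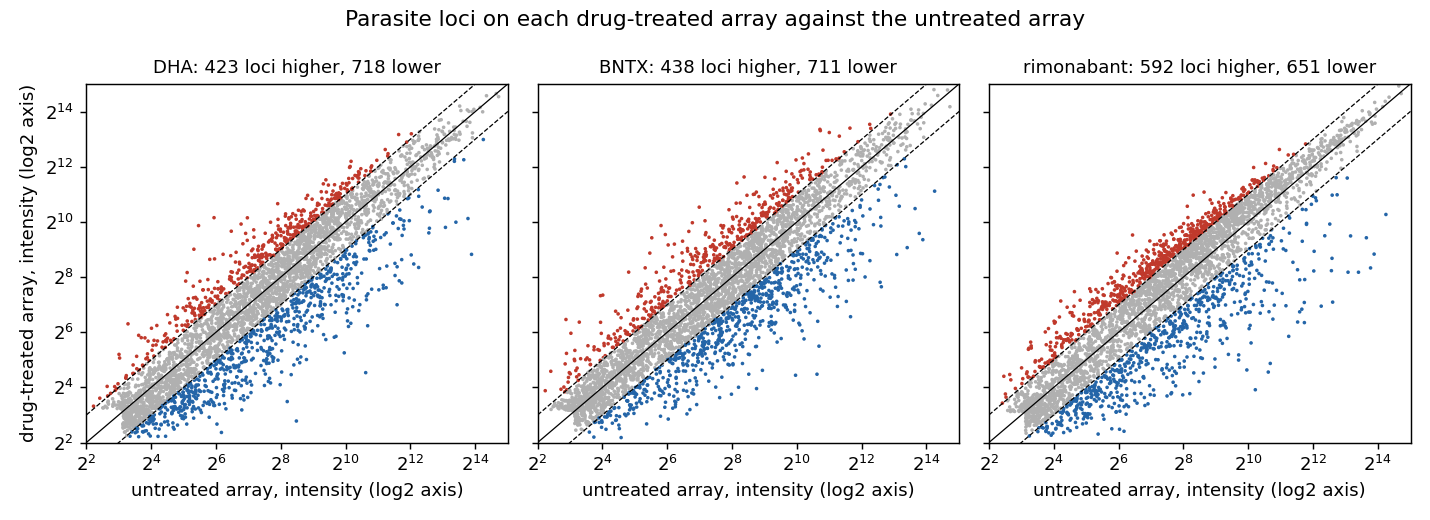
Intensity of each parasite locus on a drug-treated array (vertical, log2 axis) against the untreated array (horizontal, log2 axis), 1 panel per drug, with solid lines at equality and dashed lines at 2-fold. Red points are loci at least 2-fold higher (423 for DHA, 438 for BNTX, 592 for rimonabant) and blue points those at least 2-fold lower (718, 711 and 651), as deposited.

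BNTX was also compared with the untreated culture. Actin was 7.30-fold lower on the BNTX array, at 364 against 2656, with a log2 ratio of -2.87 ± 0.28 (SD over 3 probe sets). GAPDH was 1.52-fold higher, at 1353 against 890, with a log2 ratio of 0.60 ± 0.11. The hrpIII transcript, lower under DHA, was 1.63-fold higher under BNTX, at 84.0 against 51.6, with a log2 ratio of 0.70 ± 0.04 over 2 probe sets. All 3 directions held under both scalings.

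Pf.12.421 had the highest ratio under BNTX, 16.7-fold, at 936 against 56.1, and Pf.8.98 the next, 15.0-fold, at 688 against 46.0. Pf.5.41 was again the locus with the lowest ratio, 70.7-fold lower at 22.3 against 1575, and Pf.5.18 was 45.9-fold lower at 21.7 against 996. With 32 added before log2, their log2 ratios went from -6.14 to -4.89 and from -5.52 to -4.26. Pf.11.380, not above background under DHA, was 2.41-fold higher under BNTX than in the untreated culture, at 861 against 358.

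Of 3848 loci, 438 were at least 2-fold higher under BNTX and 711 at least 2-fold lower, with 74 and 229 at 4-fold. Higher loci made up 38.1% of those past 2-fold as deposited, 60.4% (764 higher and 500 lower) after centring and 50.5% (606 and 595) after quantile normalization. The median log2 ratio was -0.06 as deposited, 0.24 after centring and 0.095 after quantile normalization. The larger share after centring thus went with an upward shift of the BNTX ratios as a whole. The balance of directions at 2-fold was therefore not settled for this drug.

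Under rimonabant, actin was 7.25-fold lower than in the untreated culture, at 366 against 2656, with a log2 ratio of -2.86 ± 0.14 (SD over 3 probe sets). GAPDH was 2.07-fold higher, at 1843 against 890, and its log2 ratio of 1.05 ± 0.18 was 0.82 after quantile normalization. The hrpIII log2 ratio was -0.52 ± 0.08 over 2 probe sets, at 36.1 against 51.6. These 3 directions also held under both scalings. The ratio of 3' to 5' intensity, a sign of RNA integrity, was 4.41 for actin in the untreated culture, 5.37 under DHA, 6.44 under BNTX and 3.92 under rimonabant. For GAPDH it was 2.50, 2.93, 2.16 and 1.96 on the same arrays.

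**Figure D2:**
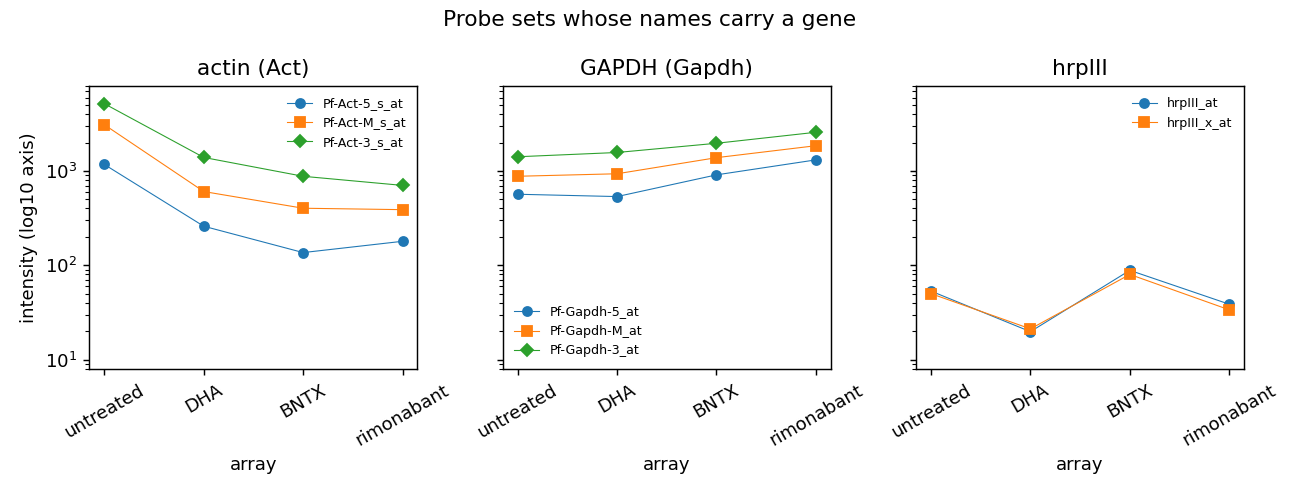
Intensity (vertical, log10 axis) on the untreated, DHA, BNTX and rimonabant arrays (horizontal) of the probe sets whose IDs name actin, GAPDH or hrpIII, 1 line per probe set. All 3 actin sets lie lower on each treated array than on the untreated one, the GAPDH sets are highest under rimonabant, and the hrpIII sets are highest under BNTX.

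The loci with the highest ratios under rimonabant were Pf.UN_4.2, 8.54-fold higher at 738 against 86.4, and Pf.2.228, 7.55-fold higher at 140 against 18.6. The lowest ratio belonged to Pf.2.48, 79.2-fold lower at 15.1 against 1194. That locus was also lower under DHA, at 122, and under BNTX, at 54.1. Pf.5.41 was 66.96-fold lower, at 23.5 against 1575. With 32 added before log2, the log2 ratios of Pf.2.48 and Pf.5.41 went from -6.31 to -4.70 and from -6.07 to -4.86. The sizes of these folds therefore depend on treated values near background. Pf.12.150, among the highest ratios under DHA, was 3.40-fold lower under rimonabant, at 18.1 against 61.4.

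Of 3826 loci, 592 were at least 2-fold higher under rimonabant and 651 at least 2-fold lower, with 47 and 220 at 4-fold. Higher loci made up 47.6% of those past 2-fold as deposited, 43.6% after centring and 48.4% after quantile normalization. As a measure of noise within an array, different probe sets of the same locus, leaving out those that can hybridise to several sequences, differed in log2 ratio with an SD of 0.66 for DHA (43 pairs), 0.63 for BNTX (46 pairs) and 0.62 for rimonabant (44 pairs). The mosquito probe sets had an SD of the log2 ratio of 0.18 for each drug, against at least 1.08 for the parasite loci under each drug. Most mosquito sets lie near background, so 0.18 is the spread there and does not measure the noise of brighter parasite loci.

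The drugs were next compared for loci that differed from the untreated culture in the same direction. All 3 treated arrays were at least 2-fold lower at 281 loci, Pf.5.41, Pf.5.18 and Pf.2.48 among them, and at least 2-fold higher at 119, which included Pf.13_1.639. At 4-fold, 91 loci were lower under all 3 drugs and 3 were higher. With each array centred, the 2-fold numbers were 235 lower and 179 higher, and after quantile normalization 258 and 172. At 4-fold the imbalance held under both scalings, with 78 lower and 4 higher after centring and 85 and 8 after quantile normalization.

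Because the comparisons share 1 untreated array, some overlap arises without any shared effect. When the 4 values of each locus, with array medians over the 3887 loci above background on any array removed, were shuffled among the arrays, a mean of 132 loci were lower on all 3 treated arrays and 121 were higher. The observed numbers on the same footing were 225 and 212, above those of each of 1000 shuffles. They differ from the numbers after centring because centring used the medians of the 3440 loci above background on all 4 arrays. As deposited the numbers were 281 and 119, so the count of higher loci depended on the removal of medians. Independent lists of the same lengths would share 22.0 lower and 7.26 higher loci. The log2 ratios across loci, which are not independent replicates, correlated at r = 0.710 between DHA and BNTX, 0.718 between DHA and rimonabant and 0.532 between BNTX and rimonabant, where shuffling gave a mean of 0.50 for each pair. The values for the pairs with DHA lay above every shuffle, while that for BNTX and rimonabant lay within the shuffled range of 0.453 to 0.551. For that pair r was 0.555 after quantile normalization, within the range shuffled under that setting (up to 0.561), and 0.587 with 32 added before log2, above it (up to 0.552). The covariances were 0.850, 0.885 and 0.686, beside shuffled means of 0.534, 0.535 and 0.534 and shuffled maxima of 0.593, 0.601 and 0.608. The share of loci with the same sign for BNTX and rimonabant, 65.7% with array medians removed, was below the shuffled mean of 66.7% and within the shuffled range of 63.8 to 69.0%. A single untreated array cannot be split, so part or all of any excess over the shuffles may come from it.

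By pairs, as deposited, DHA and BNTX shared 226 higher and 421 lower loci, DHA and rimonabant 228 and 422, and BNTX and rimonabant 158 and 337. With array medians removed, the shuffled mean rounded to 219 or 220 loci for every pair and direction. On that footing DHA and BNTX shared 413 and 312, and DHA and rimonabant 320 and 372, all above the shuffled ranges. BNTX and rimonabant shared 260 higher loci, within the shuffled range of 178 to 269, and 267 lower loci, above the shuffled maximum of 258. Because the shuffles move each locus separately, so small a margin cannot by itself be read as an excess. Independent lists of the lengths as deposited, which leave out the shared untreated array, would share 47.7 and 131.3 loci for DHA and BNTX, 64.4 and 120 for DHA and rimonabant, and 66.7 and 119 for BNTX and rimonabant. Loci past 2-fold in opposite directions numbered 13 for DHA and BNTX, 29 for DHA and rimonabant (Pf.12.150 among them), and 60 for BNTX and rimonabant. After array medians were removed the observed numbers were 37, 28 and 88, beside shuffled means of 42.6, 42.4 and 42.7. Of these, 37 and 28 lay within the shuffled ranges (23 to 59 and 25 to 58). The 88 for BNTX and rimonabant lay above the shuffled maximum of 61. As deposited this number was 60, so the excess depended on the removal of array medians. The same step raised shared higher loci, for example from 226 to 413 for DHA and BNTX. No other scaling of these pair counts is given here.

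A count that treats all 4 arrays alike was made of loci at which 1 array lay at least 2-fold above or below every other array. The untreated array stood apart in this way at 400 of 3887 loci (10.29%), 281 of them higher and 119 lower, which are by construction the loci counted above as lower or higher under all 3 drugs. The DHA array did so at 79 loci (19 higher and 60 lower), the BNTX array at 227 (107 and 120) and the rimonabant array at 253 (135 and 118). Pf.2.228 was among the loci at which rimonabant alone was higher. The division into higher and lower depended on the scaling for BNTX (199 and 69 after centring) and for rimonabant, where 68 loci were higher after centring and 88 after quantile normalization. With 32 added before log2 the totals were 287 for the untreated array, 25 for DHA, 104 for BNTX and 124 for rimonabant.

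**Figure D3:**
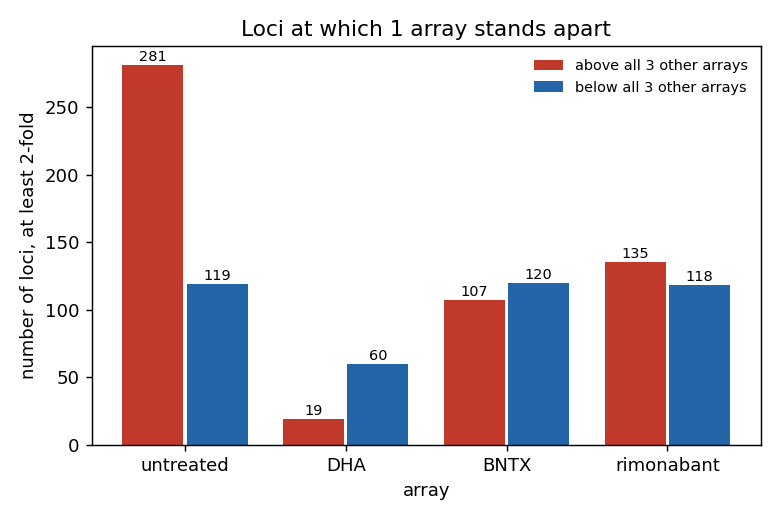
Number of parasite loci (vertical, linear axis from 0) at which the array named on the horizontal axis lay at least 2-fold above (red) or below (blue) all 3 other arrays, as deposited. The untreated array has 281 and 119 such loci and the DHA array 19 and 60.

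The treated cultures were finally compared with each other, without the untreated array. The doses are not stated, so these are not dose-matched comparisons, and the compounds are not structural analogs of each other. DHA and BNTX differed by at least 2-fold at 760 of 3793 loci, with DHA higher at 318 and lower at 442. DHA and rimonabant differed at 767 of 3731, with DHA higher at 270 and lower at 497. BNTX and rimonabant differed at 1283 of 3831, with BNTX higher at 522 and lower at 761. With 32 added before log2, which shrinks ratios of dim loci, these 3 totals were 367, 447 and 824. Pf.11.380, at 861 under BNTX, 18.5 under rimonabant and not above background under DHA, and Pf.12.150, at 1141 under DHA, 747 under BNTX and 18.1 under rimonabant, differed widely between drugs. Of the 3 treated arrays, the DHA array held the middle value at 46.4% of loci, BNTX at 26.6% and rimonabant at 26.9%, where 33.3% each would be even. Across loci, log2 intensities correlated at r = 0.953 between DHA and BNTX, 0.954 between DHA and rimonabant and 0.918 between BNTX and rimonabant, and at 0.921, 0.907 and 0.909 between the untreated array and those of DHA, BNTX and rimonabant.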

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

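The counts in this part were chosen after the data were seen, and no explanation of them was tested. They concern probe sets outside the parasite loci, in which signal lay at least 2-fold above the untreated array. Shares are to be read over the sets above background on either array compared. Among probe sets with an accession as ID and no mark RC, these numbered 179 of 591 for DHA, 190 for BNTX and 177 for rimonabant, of which 36 were at least 2-fold higher under DHA, 56 under BNTX and 17 under rimonabant, and 18, 20 and 20 were at least 2-fold lower. Among the accession sets whose IDs carry the mark RC, they numbered at least 158 for each drug, of which 5 were higher under DHA, 20 under BNTX and 12 under rimonabant, and 17, 4 and 16 were lower. Of 290 probe sets with purely numeric IDs they numbered 93, 100 and 97, of which 7 were higher under BNTX and 0 under the other drugs, and 4 were lower under DHA, 2 under BNTX and 3 under rimonabant.

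A group of 8 numeric probe sets had intensities between 5078 and 15003 on every array, far above the highest mosquito set at 123. Their median ratio to the untreated array was 0.627 under DHA, 1.46 under BNTX and 0.806 under rimonabant. Under BNTX they fell into 2 groups, with log2 ratios between -0.05 and 0.03 for 3 of them and between 0.47 and 0.71 for the other 5. The same groups differed under DHA, at -0.42 to -0.39 for the 3 and -0.76 to -0.66 for the 5. Under rimonabant they lay at -0.12 to 0.08 and at -0.55 to -0.21, so each median mixes 2 groups. What these probe sets detect is not given in the sources used here, so their ratios cannot be read as those of parasite transcripts.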

How the results depend on the processing

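All settings but 1, the raising of dim values to the background cutoff, were fixed before the data were examined. Over 8 settings, 151 values stayed close to the reported one (counts within 1.5 times, correlations within a 95% interval from the number of loci) and 25 moved, all of them under the 3 settings that follow. With each array centred on its median, 764 loci were higher under BNTX, 179 were higher under all 3 drugs (the same 179 at which the untreated array stood apart as lower), BNTX stood apart at 199 higher and 69 lower loci and rimonabant at 68 higher. Quantile normalization gave 163 higher loci for BNTX standing apart and 88 for rimonabant, with r = 0.726 for DHA and BNTX and 0.555 for BNTX and rimonabant. Adding 32 before log2, which by construction shrinks ratios of dim loci, left 438 loci lower under DHA, and 388 higher and 397 lower under rimonabant. The loci standing apart were then 7 higher and 18 lower for DHA, 54 and 50 for BNTX and 71 and 53 for rimonabant. The correlations became 0.767 for DHA and BNTX, 0.742 for DHA and rimonabant and 0.587 for BNTX and rimonabant, and the loci differing between those drugs numbered 367, 447 and 824. For centring and quantile normalization the cause was not tested. Of the values of named loci, 87 stayed within the SD between probe sets of a locus and 9 moved, each with 32 added, and none reversed. The 99th percentile cutoff and the absence of a filter removed or added almost no locus past 2-fold, so they say little about stability. Leaving out var, rifin and stevor genes and the medians of gene lists were not run, since the IDs carry no gene names. No paired analysis was possible because each group has 1 array. Signal over background limits ratios of dim loci.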

Other observations

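The count of loci at which an array stands apart and its scalings were fixed before the data were examined, and the other tests in this part were chosen after the results were seen. Loci grouped by the chromosome field of their ID differed little in median log2 ratio. Of 14 fields, 1 lay outside the central 95% of matched random lists under DHA, 2 under BNTX and 2 under rimonabant, where 0.7 would do so by chance for each drug. Field 10 was low under both DHA (median -0.29, percentile 0.37) and BNTX (-0.20, percentile 0.97). Under rimonabant it lay within the central 95% (0.08, percentile 10.84). The ratios share 1 untreated array, so the DHA and BNTX values are not independent of each other. Field 6 was low under BNTX (-0.26, percentile 0.29), field 9 low under rimonabant (-0.01, percentile 0.4) and field 14 high under rimonabant (0.26, percentile 99.46).

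For 230 accessions the array carries a probe set with and a probe set without the mark RC. In the untreated culture both were above background for 53 of them, the RC set alone for 51, the other set alone for 14 and neither for 112. The RC set alone was above background for 51 under DHA, 42 under BNTX and 53 under rimonabant.

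The untreated array stood apart from the other arrays at 400 loci, 1.58 times as many as the highest treated array. In pairs, it was not the only distant array. Log2 intensities of BNTX and rimonabant correlated at 0.918, within the range of 0.907 to 0.921 for the untreated array with the treated ones. The pairs of DHA with BNTX and with rimonabant correlated at 0.953 and 0.954. The values argue against between-array scaling as the whole cause of the higher count. The ratio of counts was still 1.54 at its lower under the 2 scalings. For RNA integrity of the untreated sample, the 3' to 5' ratio of both control transcripts, 2 of 2, lay within the range of the treated arrays. An array can lie within the range of 3 others whatever the cause, so this check cannot exclude RNA integrity. Probe-level noise on the untreated array would leave further probe sets of the same loci undisturbed, but 100% of them (7 of 7, at 7 loci, Wilson 95% lower bound 64.6%) went the same way by 2-fold. That check reached only 7 of the 400 loci, so it cannot exclude such noise at the others. A drug response shared by the 3 treated cultures may be the source, yet with 1 untreated array it cannot be told apart from a culture that differed for another reason, such as its stage or time of harvest.

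Leaving out loci whose field begins with UN, those with low numbers in their ID were more often at least 4-fold lower under all 3 drugs: 20 of 229 loci numbered 1 to 20 (8.73%, Wilson 95% interval 5.72 to 13.1%), Pf.5.18 among them, against 71 of 3648 others (1.95%, 1.55 to 2.45%). Probe sets shared between similar sequences did not account for it, as the share without _x_at and _s_at sets was 8.29% (5.31 to 12.7%). Nor did mean intensity over the 4 arrays, since 0% of 10000 random sets matched on it reached the observed share. That mean includes the 3 treated values, and brightness on the untreated array alone was not matched. The check therefore cannot exclude brightness on the untreated array. Numbering along the chromosome with a response at both ends may be put forward. The 20 highest numbers of each field showed 1.79% (0.765 to 4.11%), under the interval of the low numbers. However, the numbers ran past the count of protein-coding genes in the reference, for example to 530 against 399 on chromosome 10 and to 183 against 134 on chromosome 1. The highest numbers need not lie at a chromosome end, so this share cannot decide the question. What the numbers stand for is not given in the sources used here, and no biological explanation was tested.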
